A study of Danio rerio with 18 samples.

How the data were processed

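RNA was sequenced from intestines and kidneys dissected from zebrafish of the AB strain, 18 libraries in 6 groups of 3. Intestines were taken at 5 days after fertilization and kidneys, which hold the blood-forming tissue of this fish, at 7 days. In each tissue the groups were conventionally raised wild type (CV), germ-free wild type (GF) and chd8-/-, a mutant of the gene for a chromatin remodeller of the CHD family. Per the labels' protocols, GF embryos were washed in polyvinylpyrrolidone and hypochlorite and held for some hours in medium with antibiotics before being raised in sterile medium, while CV embryos came from the same spawned eggs without these steps. Parents of the CV and GF embryos mated in autoclaved system water, whereas parents of the chd8-/- embryos mated in circulating system water, so genotype and rearing cannot be separated. The chd8-/- samples were also listed in a separate, later block than the CV and GF samples. Any batch of collection or sequencing therefore cannot be separated from genotype either. The labels give 30 embryos for CV and GF intestine, 50 for CV and GF kidney, 40 for chd8-/- intestine and about 70 for chd8-/- kidney, without saying whether these numbers are per library. The labels number the replicates without saying that they came from separate clutches, so the p-values measure only the spread between these samples, which may be technical.

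The values used are the authors' deposited counts, whole numbers of reads per gene for 32520 Ensembl genes, in 4 tables, each holding the CV libraries and a second group of one tissue. Per the submitters' processing notes, the tools were Trim Galore 0.6.7, FastQC 0.11.9, STAR 2.7.9a, Subread 2.0.1 and featureCounts, and the genome build was GRCz11. The annotation release, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. Values of overlapping genes and of near-identical family members (such as the ifi27, ifit, herc56, mhc1 and hbae families) are therefore uncertain, since reads can be split or lost between copies. No value was taken from a column outside the 18 libraries, and no table held a line without a gene. No coordinates are printed, because no annotation of the authors' build was used, and the gene order of another assembly (GRCz12tu) served only to find which genes neighbour chd8. Symbols came from a table of gene names, which gave 29201 of the 32520 identifiers a symbol. Of these, 12591 were written in capitals, as for a human orthologue, and 6136 shared their symbol with another identifier. Symbols are printed as that table gives them, so the zebrafish genes chd8, saa and spi1b appear as CHD8, SAA2 and SPI1.

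The CV columns of both kidney tables were identical. The CV columns of both intestine tables were the same 3 libraries with other numbers and slightly different counts. Replicate 1 of the germ-free table matched replicate 3 of the chd8-/- table, with equal counts in 80.9% of the genes and absolute differences summing to 0.077% of the total count. Replicate 2 matched replicate 1 (72.8% and 0.228%), and replicate 3 matched replicate 2 (78.4% and 0.074%). Each comparison used the CV columns of its own table, and CV libraries of the intestine are named below with the table whose numbering is meant. Within every group, each pair of libraries differed by far more than sampling noise, with a chi-square per degree of freedom of at least 16.5 over genes with 20 or more counts, so no library was counted as a repeat of another.

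Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter, robust dispersion estimates and the quasi-likelihood F-test, on the 6 libraries of each comparison and without a block. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Values in CPM (counts scaled to a common library size) use the TMM factors of the 6 libraries of a comparison, or, where values of all 3 groups stand side by side, of the 9 libraries of the tissue. Every adjusted p of a gene is from edgeR unless DESeq2 is named. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation of 0.01 between genes, for lists with at least 5 measured genes. The 48 lists, of programs, cell types and signs of tissue or RNA quality, were fixed from textbook knowledge, and P-values were adjusted over the lists of a comparison. For each list the camera test was repeated with an estimated correlation and with fry. For part of the lists, the number of genes called with adjustment over the list alone is given, in most cases beside the number called among all genes.

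The edgeR, DESeq2, voom and camera steps were tested on simulated counts drawn from the means, dispersions and library sizes of these libraries, with 200 genes changed, 100 of them 2-fold and 100 of them 4-fold. In the simulated intestine comparisons, edgeR found 35% of the 2-fold and 88% of the 4-fold changes for GF (20635 genes) and 57% and 93% for chd8-/- (20375 genes). In the simulated kidney comparisons it found 10% and 64% for GF (20735 genes) and 2% and 72% for chd8-/- (20576 genes). For the tissue differences it found 3% and 49% for GF (22011 genes) and 3% and 48% for chd8-/- (21827 genes). DESeq2 found more of the changed genes than edgeR in each comparison of 6 libraries, but also called more unchanged genes. In simulated intestine DESeq2 called 40 (GF) and 38 (chd8-/-) unchanged genes, edgeR 12 and 13, and voom 9 and 12. In simulated kidney DESeq2 called 55 and 57, edgeR 7 and 11, and voom 4 and 6. Among the 48 lists of the simulated chd8-/- intestine comparison, camera called the 1 planted list and 0 others. Simulated genes varied independently of each other, so this does not check the preset correlation where genes vary together. A planted covariance between both kidney comparisons of 0.023 was estimated as 0.0214. This test was written after a first look at the real results and now precedes them, with no function changed.

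Differences between tissues were tested as the interaction of tissue with group over 12 libraries. Tissue and age are confounded in this design. Both comparisons of a tissue share their CV libraries, so the agreement of their fold changes was set beside 10 simulations of unchanged groups against the same controls, and 5 with libraries left out, added after the data were seen. The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. By that rule the text names CHD8, sentinel genes whatever their result (il1b, ANGPTL4, FABP2 and saa in intestine, gata1a, SPI1, RUNX1 and saa in kidney), the called genes with the largest changes in each direction (mean CPM of at least 5, groups not overlapping, lower-case symbol), and up to 3 called genes per list. The sentinel mpx matched no symbol and is not analysed here, and saa did not pass the filter in GF intestine. After the data were seen, the rule was extended to the 3 largest changes per direction among symbols in capitals, and, where no gene was called, to the 15 genes with a symbol and the smallest p. Other genes whose values per library are given were also chosen after their values were seen. The alternatives were DESeq2 size factors in edgeR, library size only, no filter, a stricter filter (CPM of at least 1 in at least 3 libraries), DESeq2 1.42.0, limma voom, a 2-fold minimum, a replicate block, all 3 groups of a tissue in 1 fit, and leaving out each library in turn. Fits without a pair of kidney libraries were added after the data were seen.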

Results

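Gene counts were compared in 18 zebrafish libraries, 3 each of conventionally raised wild type (CV), germ-free wild type (GF) and chd8-/-, from intestine at 5 days and kidney at 7 days after fertilization. Total counts per library ran from 26809112 to 36624972 in the intestine and from 27291597 to 31268453 in the kidney. The 10 most abundant genes took 9.9% to 10.7% of the counts in intestine libraries and 13.8% to 16.8% in kidney libraries. The design asks how gene activity in each tissue differed between fish raised with and without microbes, and between chd8-/- and wild type fish.

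CHD8, the targeted gene, was lower in all 3 chd8-/- libraries of the intestine than in any wild type library. Its level was 32.7, 35.4 and 41.9 CPM in chd8-/-, 52.8 to 57.5 CPM in CV and 59.4 to 65.3 CPM in GF intestine (TMM over 9 libraries). Over the 6 libraries of the chd8-/- comparison it fell from 54.2 ± 2.39 to 35.9 ± 4.9 CPM (SD, n = 3 each), a log2 fold change of −0.60 (SE 0.15, edgeR adjusted p = 0.0292). That call was lost without CV replicate 3 in the numbering of the chd8-/- table (−0.56, adjusted p = 0.0561), and without chd8-/- replicate 1 (−0.51, 0.158), replicate 2 (−0.57, 0.129) or replicate 3 (−0.70, 0.0598). In the kidney CHD8 stood at 28.3, 33.8 and 37.8 CPM in chd8-/- and at 45.1 to 51 CPM in CV, a log2 difference of −0.55 (SE 0.18) that did not pass (adjusted p = 0.468, but −0.49 and 0.04 without CV replicate 1 and chd8-/- replicate 1, a pair chosen after the data were seen). The GF kidney libraries held 53, 31.6 and 53.2 CPM. The library labelled kidney germ-free replicate 2 thus lay within the range of the chd8-/- libraries, against its label, and every direction drawn from GF kidney below includes it. CHD8 did not pass in GF intestine (0.20, SE 0.14, adjusted p = 0.843) or GF kidney (−0.08, SE 0.22, adjusted p = 0.929, and 0.13 without that library).

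**Figure D1:**
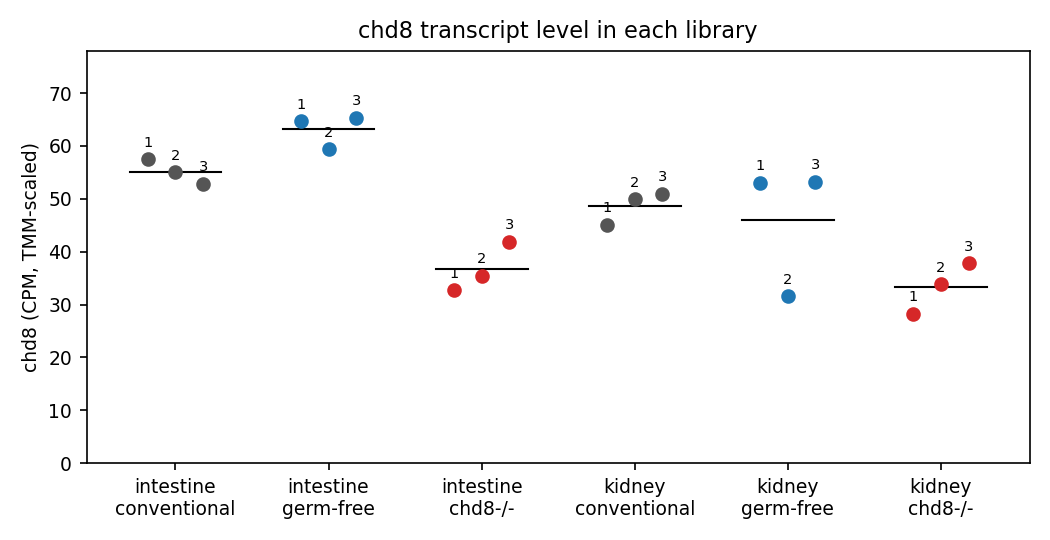
Level of the chd8 transcript (CHD8) in CPM (TMM over the 9 libraries of a tissue) in each of 18 libraries, where points are libraries with their replicate number (CV as in the germ-free tables) and lines are group means. The chd8-/- intestine libraries sit between 32.7 and 41.9 CPM, under all other intestine libraries, and the library labelled kidney germ-free replicate 2 sits at 31.6 CPM among the kidney chd8-/- libraries.

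The first question was what rearing without microbes changed in the intestine. The yolk precursor gene vtg7 stood at 1.75 ± 0.656 CPM in CV and 13.2 ± 2.54 CPM in GF intestine (n = 3 each, log2 difference 2.92, SE 0.31), and the cytochrome P450 gene cyp2k6 at 22.3 ± 2.28 and 68.0 ± 13.8 CPM (1.61, SE 0.19). Neither passed in edgeR (adjusted p = 0.0523 for both), although both did in DESeq2 (7.82e-15 and 3.64e-10), in edgeR without GF replicate 3 (0.03 for both), and in edgeR with library size only, without a filter, with the stricter filter or with all 3 groups in 1 fit (0.00794 to 0.0497). The heat shock gene hsp70l stood at 2.57 CPM in CV and 15.7 CPM in GF (2.59, SE 0.46), while the immediate early and heat shock list did not pass (18 of 44 genes positive, median −0.10, camera adjusted p = 0.0875). The transcription factor gene irf1b of the interferon pathway was at 23.1 CPM in CV and 7.89 CPM in GF (−1.55, SE 0.31), and dio3b, whose enzyme inactivates thyroid hormone, at 35.5 and 81.0 CPM (1.19). These 3 genes had an adjusted p of 0.803 in edgeR and passed in DESeq2 (5.74e-06, 0.00243 and 0.0139). The sentinel genes did not pass, with il1b at −0.91 (SE 0.67, adjusted p = 0.843), the fatty acid binding gene FABP2 at −0.12 (SE 0.27, 0.953, and 0.12 without CV replicate 1) and ANGPTL4 at −0.004 (SE 0.26, 0.999).

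Of 20954 genes tested in GF intestine, edgeR called 0, voom called 0 and DESeq2 called 35 (12 higher and 23 lower in GF). In the simulation of this comparison DESeq2 called 40 unchanged genes. That simulation also held changed genes, and calling these eases the adjusted threshold for the others. The 40 is therefore no estimate of the false calls among the 35. Without CV replicate 3 or GF replicate 3 edgeR called 2. An unadjusted p under 0.05 was found for 1249 genes, against 1048 by chance. Among 48 gene lists, camera called 9 higher and 10 lower, and 0 held with an estimated correlation. The interferon-response list was lower in GF, with 31 of 36 genes negative and a median log2 difference of −0.90 (camera adjusted p = 5.72e-13, adjusted p = 0.705 with an estimated correlation). Its genes called were 0 over all genes and 1, lower, adjusted over the list alone. The enterocyte list was lower in 28 of 31 genes (median −0.36, adjusted p = 9.59e-08, adjusted p = 0.705 with an estimated correlation). The inflammation list was lower in 32 of 35 genes (median −0.28, 5.57e-05 and 0.705), with medians of −0.47 without CV replicate 2 and −0.43 without GF replicate 3. Genes encoded in mitochondria were lower in 12 of 13 (−0.27, 0.0117 and 0.709). Clock genes were higher in 26 of 36 (0.14, 0.00498 and 0.705) and proliferation genes in 43 of 51 (0.23, 0.000125 and 0.733). Each of these last lists lost its call without a single library: CV replicate 2 for mitochondria (0.336) and proliferation (0.479), and CV replicate 1 for the clock (0.125). The list of brain and retina markers had a median of 2.44 (0.00274, and 0.709 with an estimated correlation). It rested on GF replicate 3, which stood at 2.87 on the list's mean log2 scale beside −0.41 and −0.61 in the other GF libraries, and without which the median was −0.04 (adjusted p = 0.767). The same library held 75.2 CPM of opn1mw1, a cone opsin gene, and 20.2 CPM of the lens crystallin gene crygm2d1, where the other CV and GF intestine libraries held 0 CPM of both. The enteric neuron list likewise had a median of 0.70 (0.0117, and 0.733 with an estimated correlation), and −0.05 without that library (0.497).

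The same question was asked of the kidney, the blood-forming organ of this fish. FKBP5 and KLF9, both textbook targets of the glucocorticoid receptor, stood at 152 ± 4.42 and 176 ± 7.13 CPM in CV and at 55.6 ± 13.2 and 76.5 ± 12.7 CPM in GF kidney (n = 3 each, log2 differences −1.45, SE 0.20, and −1.21, SE 0.18). The glucocorticoid list was called by camera with a median of only −0.24. That median was −0.72 without the library labelled kidney germ-free replicate 2 and −0.08 without GF replicate 1. The interferon-induced genes RSAD2 and helz2a stood at 4.77 and 9.80 CPM in CV and at 0.238 and 1.00 CPM in GF (−4.29, SE 0.59, and −3.29, SE 0.45). PALMD (2.27 ± 0.138 to 9.57 ± 1.76 CPM, 2.08, SE 0.25) and TGFBI, which encodes an extracellular matrix protein (54.4 to 136 CPM, 1.32, SE 0.23), were higher in GF. None of these 6 passed in edgeR, where adjusted p ran from 0.298 for PALMD to 0.411 for TGFBI, and all passed in DESeq2, where it ran from 1.33e-09 for RSAD2 to 0.000228 for TGFBI. All 6 were also called by edgeR with CV replicate 1 and the library labelled kidney germ-free replicate 2 both left out, a fit chosen after the data were seen. The sentinel genes did not pass: gata1a, a regulator of red cell formation, at 1.02 (SE 0.49, adjusted p = 0.586, but called in that fit at 1.27, adjusted p = 0.0255), the myeloid regulator SPI1 at −0.33 (0.837, and 0.42 without CV replicate 1), the stem cell regulator RUNX1 at 0.17 (0.934, −0.010 without CV replicate 3 and −0.17 without GF replicate 3) and the acute phase gene SAA2 at −0.21 (0.947, 0.56 without CV replicate 1 and 0.25 without GF replicate 3).

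Of 21120 genes tested in GF kidney, edgeR and voom called 0 and DESeq2 called 176 (70 higher and 106 lower in GF). In the simulation of this comparison, which also held changed genes, DESeq2 called 55 unchanged genes. As in the intestine, this is no estimate of the false calls among the 176. An unadjusted p under 0.05 was found for 1856 genes, against 1056 by chance, and the groups did not overlap in 15.3% of genes, against 10% by chance. Camera called 17 lists higher and 11 lower (18 in all without CV replicate 1), and 0 held with an estimated correlation (adjusted p = 0.714 for each list below). The interferon-response list was lower in GF in 31 of 34 genes, with a median of −1.59 (adjusted p = 6.2e-16) and 0 genes called over all genes but 19, all lower, adjusted over the list alone. CV replicate 1 stood at 1.52 on the list's mean log2 scale beside 0.31 and 0.38 in the other CV libraries, and the median was −0.65 without it. The antigen presentation list (−1.02, 0.000279) and the inflammation list (−0.58, 0.000611) were not called without that library (−0.18, adjusted p = 0.15, and 0.05, adjusted p = 0.612). The inflammation median was −0.88 without CV replicate 2 and −1.03 without the library labelled kidney germ-free replicate 2. With both that library and CV replicate 1 left out, a fit chosen after the data were seen, the inflammation list was called and the antigen presentation list was not (adjusted p = 0.115). The immediate early and heat shock list was lower in 37 of 44 genes (median −0.68, 3.25e-07, and −1.08 without CV replicate 2). The endothelium list was higher in 25 of 27 genes (0.31, 6e-08), with 6 genes called adjusted over the list alone, and the fatty acid oxidation list in 31 of 40 (0.33, 7.61e-05). The erythroid list was higher in 31 of 38 genes (0.42, 0.00757), but not called without CV replicate 3 (0.104) or GF replicate 1 (0.20, adjusted p = 0.166). On its mean log2 scale the library labelled kidney germ-free replicate 2 stood at −0.43 beside 0.62 and 0.29 in the other GF libraries. Markers of neurons were higher as well, with the enteric neuron list positive in 33 of 34 genes (0.74, 5.77e-07) and the list of brain and retina markers in 16 of 16 (1.25, 2.44e-05, and 0.83 without GF replicate 1). For the latter GF replicates 1 and 3 stood at 0.99 and 0.87 and the library labelled kidney germ-free replicate 2 at −0.31, beside −0.75 to −0.23 in CV.

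CV replicate 1 of the kidney also stood apart in single genes. It held 704 CPM of the epithelial keratin gene krt4, 12.8 CPM of the clock gene PER1 and 288 CPM of the macrophage gene MPEG1, where the other 8 kidney libraries held 3940 to 6190, 127 to 249 and 13.3 to 47.9 CPM. The exocrine pancreas list was lower in GF kidney in 27 of 30 genes (median −0.36, camera adjusted p = 1.21e-06, adjusted p = 0.714 with an estimated correlation). The library labelled kidney germ-free replicate 2 stood at 0.51 on its mean log2 scale beside −0.46 and −0.71 in the other GF libraries. The median was −0.79 without that library, −0.24 without GF replicate 1 and −0.16 without GF replicate 3.

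**Figure D2:**
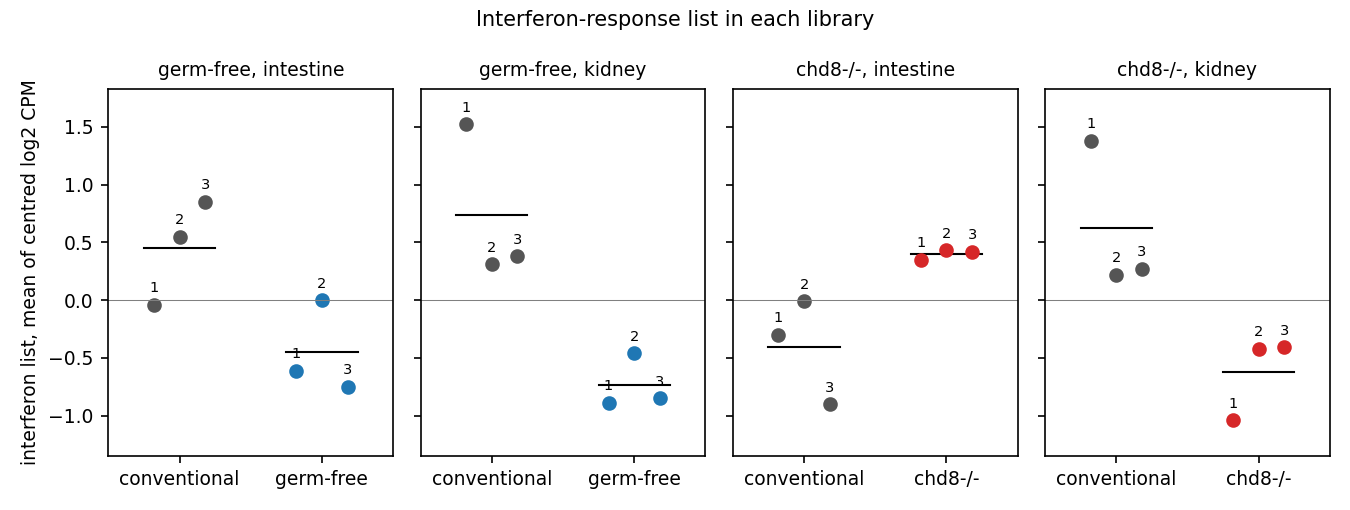
Mean of the centred log2 CPM of the interferon-response list in each library of the 4 comparisons, where points are libraries with the replicate number of that comparison's table and lines are group means. GF libraries lie lower than CV libraries on average in both tissues, CV replicate 1 of the kidney stands highest at 1.52, and chd8-/- libraries lie above CV libraries in the intestine and below them in the kidney.

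The third comparison asked what differed between chd8-/- and CV intestine, and it was the one in which edgeR called genes. The interferon-induced gene isg15, whose product is attached to proteins in antiviral responses, rose from 10.22 ± 2.66 to 55.4 ± 5.52 CPM (n = 3 each, log2 fold change 2.44, SE 0.21, adjusted p = 8.81e-05), as did ifit14 from 5.97 to 43.3 CPM (2.86, SE 0.27, 0.000204) and ifi27.6 from 0.557 to 14.1 CPM (4.69, SE 0.31, 2.21e-05). The complement gene c3a.2 fell from 414 ± 117 to 73.4 ± 23.6 CPM (−2.50, SE 0.28, 0.000532) and the complement gene bfb from 27.7 to 2.98 CPM (−3.21, SE 0.27, 8.37e-05). The related gene tep1 fell from 43.2 ± 10.6 to 4.27 ± 0.4 CPM (−3.34, SE 0.21, 1.55e-05). Of the proliferation list, TOP2A, for a DNA topoisomerase, fell from 32.16 ± 4.45 CPM in CV (−1.40, SE 0.16, 0.000439) and POLA1, for a DNA polymerase subunit, from 26.9 to 10.9 CPM (−1.31, SE 0.19, 0.00222). The epithelial oxidase gene duox rose from 0.711 to 6.83 CPM (3.25, SE 0.28, 0.000104).

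Of 20758 genes tested, edgeR called 826 higher and 1077 lower in chd8-/- intestine, 1903 in all, of which 1154 changed at least 2-fold. DESeq2 called 2748 and voom 1805, 5116 genes had an unadjusted p under 0.05 against 1038 by chance, and the groups did not overlap in 30.3% of genes against 10% by chance. With library size as the only scaling, the median log2 fold change of all genes moved by −0.125, and the calls split into 577 higher and 1555 lower. Leaving out 1 library gave 741 to 3069 calls: 3069 without CV replicate 1 and 1261 without CV replicate 2 in the numbering of the chd8-/- table, and 829, 783 and 741 without chd8-/- replicates 1, 2 and 3. Other large rises were those of GGACT (3.65, SE 0.19, adjusted p = 3.74e-06, for 1 of 3 genes with this symbol), herc56.1 (3.48), CMPK2 (3.06, SE 0.36, 0.000699), GABPB1 (2.90), mhc1zda (2.77), a class I histocompatibility gene, and the annexin gene anxa1b (2.76, SE 0.19, 2.34e-05). Other large falls were those of nat8l2 (−4.08, SE 0.31, 4.25e-05), tcnbb, a vitamin B12 carrier gene (−3.76, SE 0.36, 0.000419), CAPN7 (−3.35, SE 0.19, 5.4e-06), SPPL2B (−2.89), tenm1 (−2.89) and anxa3b (−2.85). The sentinel genes did not pass over all libraries. ANGPTL4 stood at 0.66 (SE 0.26, adjusted p = 0.139, but 0.98 and 0.027 without CV replicate 3), il1b at −1.20 (0.317, but −1.69 and 0.038 without CV replicate 1), SAA2 at −0.96 (0.431) and FABP2 at 0.18 (0.715, and −0.02 without CV replicate 1).

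Camera called 13 lists higher and 4 lower in chd8-/- intestine, and 0 of them held with an estimated correlation. The proliferation list fell most, with 28 of 51 genes lower, 0 higher and 23 not passed (44 lower adjusted over the list alone) and a median of −1.01 (camera adjusted p = 1.81e-16, adjusted p = 0.834 with an estimated correlation). RRM2, for nucleotide supply in replication, fell from 7.38 to 1.08 CPM (−2.77, SE 0.39, 0.0018, for 1 of 2 genes with this symbol). Of 37 interferon-response genes 13 rose, 2 fell and 22 did not pass (18 higher and 4 lower adjusted over the list alone), with a median of 0.58 (0.000497, and adjusted p = 0.892 with an estimated correlation), or 1.27 without CV replicate 2. Of 33 complement and acute phase genes 1 rose, 9 fell and 23 did not pass (1 and 10 adjusted over the list alone), with a median of −0.32 (0.0023, and 0.892 with an estimated correlation), or −0.48 without chd8-/- replicate 1. The ribosome biogenesis list was higher, with 6 of 44 genes called, all higher (10 adjusted over the list alone), and a median of 0.30 (0.000287, and 0.834 with an estimated correlation). Its examples depended on single libraries: BOP1 (0.75, SE 0.16, edgeR adjusted p = 0.0148) missed the threshold without chd8-/- replicate 1 (0.0694) or replicate 3 (0.0782).

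Of 38 erythroid genes 2 rose, 10 fell and 26 did not pass (3 and 16 adjusted over the list alone), with a median of −0.40 (camera adjusted p = 0.000497, adjusted p = 0.834 with an estimated correlation). The globin gene hbae1.1 fell from 4.67 to 0.397 CPM (−3.55, SE 0.38, 0.000342) and the blood gene hemgn from 22.8 to 8.72 CPM (−1.39, SE 0.17, 0.000699). Of 2 genes with the anion exchanger symbol SLC4A1, 1 rose (1.27, SE 0.18, 0.00207) and the other stood at −0.75. Which of them is the red cell gene was not examined. The enteroendocrine list was higher, with 4 of 32 genes called, all higher (6 adjusted over the list alone), and a median of 0.28 (0.0116, and 0.834 with an estimated correlation), or 0.15 without CV replicate 3. In the enterocyte list 4 of 31 genes rose and 2 fell (6 and 2 adjusted over the list alone), and its median of 0.25 (0.0125, and 0.892 with an estimated correlation) was not called without CV replicate 3 (0.0535) or chd8-/- replicate 2 (0.16, adjusted p = 0.0809). In that list ceacam1, a cell adhesion gene, rose from 199 to 433 CPM (1.12, SE 0.17, 0.00268). The Wnt target list was higher in 26 of 28 genes (median 0.25, 0.00261, and 0.892 with an estimated correlation), with 2 called over all genes and 2 adjusted over the list alone. One of them, notum1b, a secreted Wnt inhibitor, rose from 11.3 to 23.1 CPM (1.03, SE 0.18, 0.0059). Of 11 genes of the CHD family 3 fell and 8 did not pass (6 lower adjusted over the list alone), with a median of −0.45 (0.0097, and 0.834 with an estimated correlation), not called without CV replicate 1 (0.0988). Besides CHD8 these were chd6 (−0.73, SE 0.17, adjusted p = 0.022) and CHD1L (−0.70, SE 0.17, 0.0263), each not called without any 1 of the chd8-/- libraries (0.0762 to 0.131). The macrophage list did not pass (median 0.26, adjusted p = 0.11). Parents of chd8-/- and CV fish mated in different water and the chd8-/- samples were listed separately, so these differences follow genotype, rearing and any batch alike.

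Markers of other cell types were higher in chd8-/- intestine as well, by the camera test with the preset correlation, but each list below lost its call without at least 1 library (CV numbered as in the chd8-/- table). The exocrine pancreas list had 1 of 30 genes called, higher (1 adjusted over the list alone), and a median of 0.40 (camera adjusted p = 0.0142, adjusted p = 0.892 with an estimated correlation), and was not called without CV replicate 1 (0.25, adjusted p = 0.32) or chd8-/- replicate 1 (0.23, 0.136). The endocrine pancreas list had 1 of 11 called, higher (4 adjusted over the list alone), and a median of 0.55 (0.025, and 0.834 with an estimated correlation), and was not called without CV replicate 1 (0.0988) or chd8-/- replicate 2 (0.31, 0.0848). Of 21 pigment cell genes 1 rose (2 adjusted over the list alone), with a median of 0.44 (0.0132, and 0.892 with an estimated correlation), not called without CV replicate 2 (0.0816) or chd8-/- replicate 1 (0.131). Of 40 skeletal muscle genes 3 rose (3 adjusted over the list alone), with a median of 0.22 (0.0116, and 0.892 with an estimated correlation), not called without CV replicate 1 (0.07, 0.336). Of 39 kidney tubule genes 1 rose (0 adjusted over the list alone), with a median of 0.25 (0.0125, and 0.834 with an estimated correlation), not called without CV replicate 3 (0.117) and at 0.39 without chd8-/- replicate 1. The ribosomal protein list was higher, although 0 of its 80 genes were called higher and 2 lower (0 and 1 adjusted over the list alone), with a median of 0.21 (0.00288, and 0.907 with an estimated correlation), 0.65 without CV replicate 3 and not called without CV replicate 1 (−0.03, 0.878). Of 100 nuclear genes of oxidative phosphorylation 2 rose and 1 fell (0 and 1 adjusted over the list alone), with a median of 0.11 (0.0097, and 0.907 with an estimated correlation), not called without CV replicate 1 (−0.004, 0.787), CV replicate 2 (0.0567) or chd8-/- replicate 1 (0.07, 0.104). That median was 0.40 without CV replicate 3 and 0.19 and 0.17 without chd8-/- replicates 2 and 3.

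**Figure D3:**
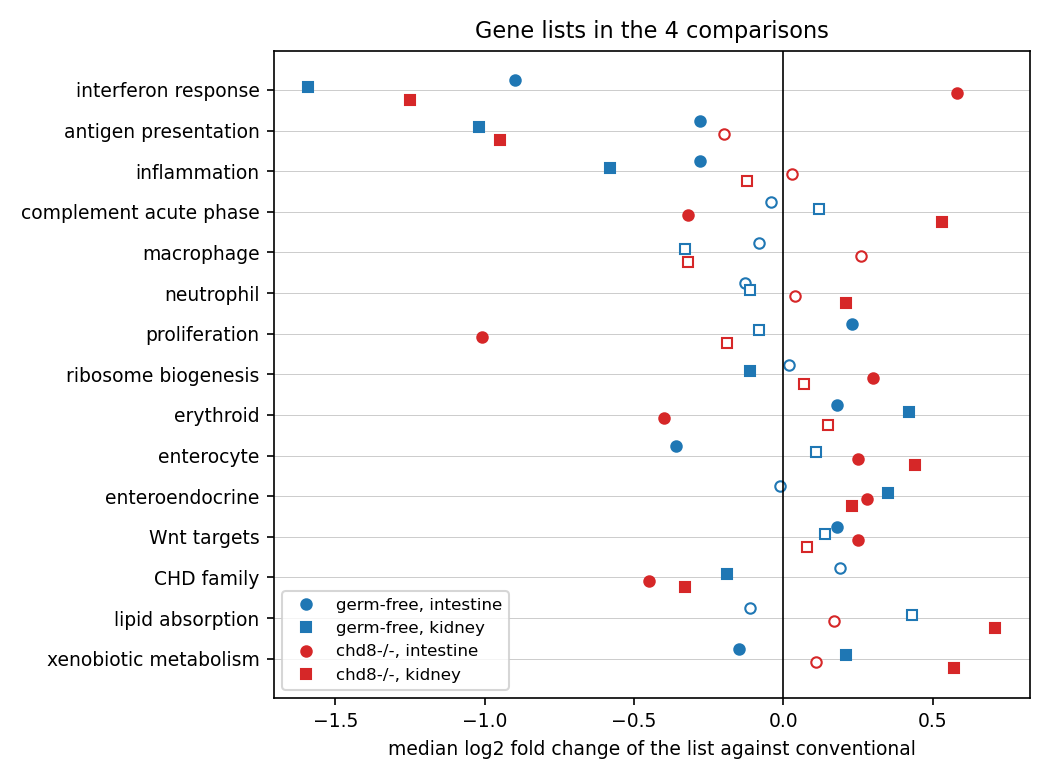
Median log2 fold change against CV for 15 gene lists in the 4 comparisons, with circles for intestine and squares for kidney, blue for germ-free and red for chd8-/-; filled symbols passed the camera test at an adjusted p under 0.05 with the preset correlation and open symbols did not. The interferon-response list lies at −0.90, −1.59 and −1.25 in GF intestine, GF kidney and chd8-/- kidney and at 0.58 in chd8-/- intestine, and the proliferation list lies at −1.01 in chd8-/- intestine.

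The fourth comparison asked the same of chd8-/- and CV kidney. The gene scpp5, for a secreted calcium-binding phosphoprotein of teeth and scales, stood at 0.624 CPM in CV and 25.0 ± 8.7 CPM in chd8-/- (n = 3 each, log2 difference 5.31, SE 0.53), the hatching enzyme gene hce2l2 at 0.0665 and 3.47 CPM (5.60, SE 0.71) and the parvalbumin gene pvalb9 at 15.3 and 56.3 CPM (1.88, SE 0.23). The cytochrome P450 gene cyp2x8 stood at 0.976 and 5.31 CPM (2.44, SE 0.34) and selenop2, for a selenium transport protein, at 41.4 and 125 CPM (1.59, SE 0.23). These 5 had adjusted p of 0.0644 to 0.227 in edgeR, and from 0.0168 for scpp5 and pvalb9 to 0.0407 for cyp2x8 without chd8-/- replicate 1. In GF kidney scpp5 stood at 27.7 and 26.1 CPM in GF replicates 1 and 3 and 3.3 CPM in the library labelled kidney germ-free replicate 2, against 0.214 to 0.949 CPM in CV (log2 difference 4.90, SE 0.88, edgeR adjusted p = 0.411, DESeq2 1.1e-08). There hce2l2 (3.83, SE 1.00) and pvalb9 (1.28, SE 0.32) likewise did not pass in edgeR (0.542 for both) and passed in DESeq2 (0.0339 and 0.0393). The transcription factor gene MAFA stood at 73.7 and 29.0 CPM (−1.35, SE 0.22, adjusted p = 0.37) and the interferon-induced gene helz2a at 9.59 and 1.35 CPM (−2.82, SE 0.48, 0.398). The pigment gene pmela differed by 1.51 (SE 0.25, 0.37, and 0.0469 without chd8-/- replicate 1). These 8 genes passed in DESeq2, from 5.39e-25 for scpp5 to 0.000218 for pmela, and in edgeR with CV replicate 1 and chd8-/- replicate 1 both left out, a fit chosen after the data were seen. SAA2 did not pass in edgeR (2.86, SE 0.83, 0.443) but did in DESeq2 (0.0232) and in that fit (4.12, adjusted p = 0.000163), at 0.866, 4.44 and 8.22 CPM in the 3 chd8-/- libraries. Nor did gata1a (0.65, 0.589), SPI1 (−0.42, 0.809, and 0.32 without CV replicate 1) or RUNX1 (0.17, 0.93, −0.006 without CV replicate 3 and −0.04 without chd8-/- replicate 3).

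Of 21060 genes tested in chd8-/- kidney, edgeR and voom called 0 and DESeq2 called 245 (140 higher and 105 lower). In the simulation of this comparison, which also held changed genes, DESeq2 called 57 unchanged genes. As for GF, this is no estimate of the false calls among the 245. An unadjusted p under 0.05 was found for 1895 genes, against 1053 by chance, and the groups did not overlap in 15.8% of genes, against 10% by chance. Without chd8-/- replicate 1 edgeR called 139 genes and without CV replicate 3 it called 3. Camera called 21 lists higher and 5 lower, and 0 held with an estimated correlation. The interferon-response list was lower in 31 of 35 genes (median −1.25, adjusted p = 2.59e-10, adjusted p = 0.366 with an estimated correlation), with 0 called over all genes and 4 adjusted over the list alone. The median was −0.36 without CV replicate 1. Lists of metabolism were higher: xenobiotic metabolism in 42 of 46 genes (median 0.57, 9.5e-11, and 0.235 with an estimated correlation) and lipid absorption in 32 of 35 (0.71, 7.45e-10, and 0.235), of which 8 were called adjusted over the list alone. The enterocyte list was higher with them, in 25 of 30 genes (0.44, 6.83e-05, and 0.392), with 8 called adjusted over the list alone, but was not called without chd8-/- replicate 1 (0.24, adjusted p = 0.0574). The fatty acid oxidation list was also called higher (median 0.31, camera adjusted p = 0.0308). It was not called without CV replicate 1 (0.359) and turned without chd8-/- replicate 1 (−0.075, adjusted p = 0.4). The list of liver markers was higher in 34 of 36 genes (0.60, 1.54e-10, and 0.392) and the complement list in 29 of 35 (0.53, 1.82e-05, and 0.26). All 13 measured genes encoded in mitochondria were higher (0.35, 1.82e-05, and 0.309), and all 11 CHD family genes lower (−0.33, 0.00024, and 0.235). The antigen presentation list was lower (−0.95, 0.00149, and 0.645), but not without CV replicate 1 (0.15, adjusted p = 0.781) and not called without chd8-/- replicate 1 (0.0917).

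Some genes were on or off by group in the intestine. With TMM over the 6 libraries of the chd8-/- intestine comparison, 14 genes had over 1 CPM in every chd8-/- and under 0.1 CPM in every CV library, and 19 genes the reverse. The counts above 0.5 CPM that follow use TMM over the 9 libraries of a tissue. The GF intestine libraries held 0, 3 and 0 of the 14 above 0.5 CPM and 18 or 19 of the 19, the 3 being in GF replicate 2. In the kidney, chd8-/- replicates 2 and 3 held 11 and 13 of the 14 genes above 0.5 CPM and 2 of the 19 each. The CV libraries and GF replicates 1 and 3 held 0 of the 14 and 16 to 18 of the 19. The library labelled kidney germ-free replicate 2 held 12 of the 14 and 1 of the 19, and chd8-/- replicate 1 held 0 of the 14 and 16 of the 19. On the mean log2 scale of the lists, chd8-/- replicate 1 stood apart from replicates 2 and 3 for the erythroid list (0.77 beside −0.46 and −0.38) and the ribosome biogenesis list (−0.51 beside 0.29 and 0.24). It lay with them for CHD8. With CV replicate 1 and chd8-/- replicate 1 both left out, a fit chosen after the data were seen, edgeR called 1082 genes higher and 1096 lower in chd8-/- kidney.

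**Figure D4:**
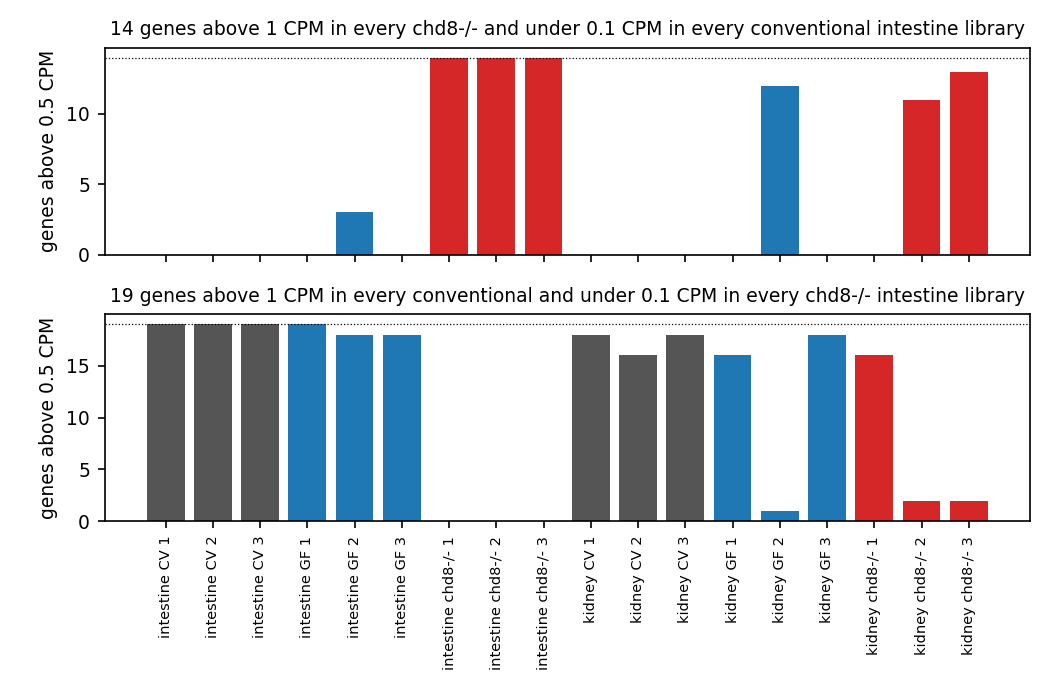
Number of genes above 0.5 CPM in each of the 18 libraries, as bars, among 14 genes on only in chd8-/- intestine (upper panel) and 19 genes on only in CV intestine (lower panel), with dotted lines at 14 and 19. The library labelled kidney germ-free replicate 2 holds 12 and 1 of them and kidney chd8-/- replicate 1 holds 0 and 16, unlike the other libraries of their groups.

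Whether the response differed between tissues was tested as an interaction of tissue with group. For chd8-/-, the interferon-induced genes isg15 and ifit8 differed between tissues: isg15 rose in intestine (2.44) and stood at −1.62 in kidney, a difference of −4.05 (SE 0.40, edgeR adjusted p = 0.00104). By library, isg15 stood at 49.8 to 60.3 CPM in chd8-/- intestine, and in the kidney at 1.43 to 3.24 CPM in chd8-/- and 6.44 to 9.75 CPM in CV (n = 3 each, TMM over 9 libraries). For ifit8 the fitted values were 3.06 and −7.78, of which the kidney value depends on the prior count and is no bound (adjusted p of the difference 0.00161), and for igldcp they were 2.63 and −3.84 (difference −6.44, SE 0.66, 0.00104). Going the other way, cyp2x8 stood at 0.42 in intestine and 2.44 in kidney (difference 2.04, SE 0.26, 0.00465) and hce2l2 at 0.37 and 5.60 (5.25, SE 0.69, 0.00579). Of 22203 genes tested, edgeR called 34, of which 15 were more positive and 19 more negative in kidney, and 28 had opposite signs in the tissues. Of 37 interferon-response genes, 3 were called and 32 were more negative in kidney. Leaving out 1 library gave 13 to 64 calls: 22, 18, 16, 16 and 13 without intestine CV replicates 2 and 3 (numbered as in the chd8-/- table) and chd8-/- replicates 1, 2 and 3, and 64 without kidney chd8-/- replicate 1. In GF kidney, against the same CV libraries, isg15 held 1.35 to 4.35 CPM and igldcp stood at −3.33. For these genes the kidney side was thus not particular to chd8-/-. Tissue and age are confounded, so the differences between tissues follow either. For GF, edgeR called 0 of 22368 genes, 1291 had an unadjusted p under 0.05, and no other tool was run. KLF9 stood at 0.75 in GF intestine and −1.21 in GF kidney, which includes the library labelled kidney germ-free replicate 2 (difference −1.90, SE 0.30, adjusted p = 0.143). Without that library 2 genes were called.

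**Figure D5:**
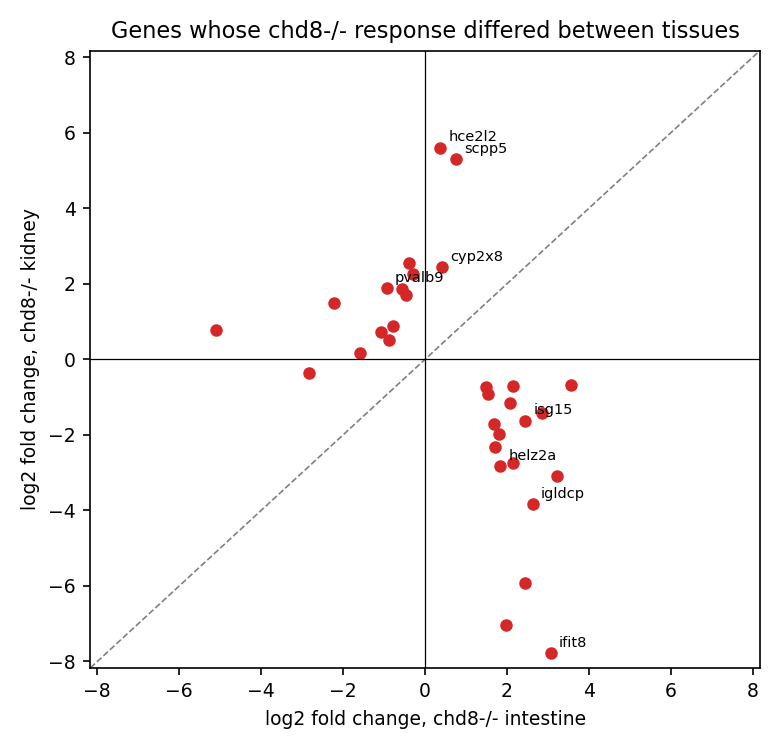
Log2 fold change against CV in chd8-/- intestine (horizontal) and chd8-/- kidney (vertical) of the genes called as different between tissues that were measured in both, where points are genes and the dashed line marks equal changes. Of the 34 called genes, 17 were higher in intestine and lower in kidney, among them isg15 at 2.44 and −1.62, and 11 the reverse.

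The GF and chd8-/- comparisons of a tissue share their CV libraries. In the intestine, the log2 fold changes of both comparisons correlated at 0.293 over 20439 genes, which are not independent replicates, against 0.512 in simulations of unchanged groups with the same controls. The covariance was 0.119 against 0.072 simulated, a difference of 0.047. That difference moved with single libraries. Set against simulations with the same library left out, it was 0.107, 0.095 and 0.019 without CV replicates 1, 2 and 3 of the germ-free table (covariances 0.224, 0.214 and 0.137 against 0.117, 0.119 and 0.118), and 0.077 and 0.015 without GF replicates 1 and 3. In the kidney the correlation was 0.708 over 20753 genes, against 0.508 simulated, and the covariance 0.273 against 0.112, a difference of 0.161, which was 0.065 without CV replicate 1 (0.254 against 0.189) and 0.271 without CV replicate 3 (0.463 against 0.192). Without the library labelled kidney germ-free replicate 2 and chd8-/- replicate 1, chosen after the data were seen, the kidney correlation was 0.326 against 0.409 simulated and the covariance 0.227 against 0.131, a difference of 0.096. In edgeR 0 genes were called in both comparisons of either tissue. In DESeq2, 15 genes were called in the same direction in both intestine comparisons (2 higher and 13 lower, against 0.685 and 1.68 for independent lists) and 3 in opposite directions. In the kidney 46 were (13 higher and 33 lower, against 0.426 and 0.531). With 3 controls no split leaves 2 in each part, so part of the excess may come from the shared controls.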

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

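The tests of exchanged labels, mixed RNA, different parents, shared growth protocols, loss of chd8 and fewer immune cells were chosen after the results were seen, as was the joint permutation over lists, whereas those of genes near chd8, of single CV libraries, of reassigned GF labels and of other splits were set beforehand. The growth protocol test replaced another test of batches after the score of a library had been seen. Matching of synonyms, the bound on calls that could not be placed near chd8, the quartile condition on immune cell lists and the reading of the permutation p as undecided were also changed afterwards. Beforehand, a permutation p under 0.05 was to speak against chance. That reading was wrong because the interferon list had been picked from 48 lists once medians were known.

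The response to chd8-/- differed between kidney and intestine for 34 genes by the edgeR interaction test, and named genes among them follow as the log2 fold change in kidney minus that in intestine. More negative in kidney were isg15 (−4.05), igldcp (−6.44), ifit8 (−10.93, a fitted value that depends on the prior count and is no bound), ifi27.6 (−6.13, under the filter in the kidney comparison) and helz2a (−4.63). More positive in kidney were cyp2x8 (2.04), hce2l2 (5.25), pvalb9 (2.83) and scpp5 (4.57). The calls of isg15, igldcp, ifit8, cyp2x8 and hce2l2 held without any 1 of the 12 libraries. That of ifi27.6 (adjusted p = 0.0298) was lost without intestine CV replicates 1, 2 and 3 (0.0612, 0.0971 and 0.0823) and chd8-/- replicates 1, 2 and 3 (0.0711, 0.0956 and 0.101), and without kidney CV replicate 2 (0.0622) and chd8-/- replicate 3 (0.0547). That of helz2a (0.0351) was lost without intestine CV replicates 1 and 2 (0.0576 and 0.0573) and chd8-/- replicates 1, 2 and 3 (0.0981, 0.102 and 0.0977), and without kidney CV replicate 1 (0.0513) and chd8-/- replicates 1 and 3 (0.0853 and 0.0903). That of pvalb9 (0.0432) was lost without intestine chd8-/- replicates 1, 2 and 3 (0.0981, 0.132 and 0.167), kidney CV replicates 1, 2 and 3 (0.0686, 0.0563 and 0.0726) and kidney chd8-/- replicates 2 and 3 (0.0694 and 0.0757). That of scpp5 (0.0459) held only without intestine CV replicate 1 (0.0432) or kidney chd8-/- replicate 2 (0.038), with adjusted p of 0.0506 to 0.163 without each of the other 10 libraries. Intestine CV replicates are numbered here as in the chd8-/- table.

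Other splits of the libraries were tried for each comparison. For the tissue difference of the chd8-/- response, 1 of 40 splits, the real one, gave as many as 34 calls and the highest other gave 3. That is a share under 0.05. Each other split mixed chd8-/- and CV libraries within at least 1 tissue, so the difference between the groups adds to its spread. Few calls are likely in such splits whatever the tissues do, so chance is not excluded. For the GF response the real split gave 0 calls, so all 40 of 40 splits give at least as many (highest other 0) and the count decides nothing. The 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 1903 calls in chd8-/- intestine (highest other 0), 0 in GF intestine (highest other 1), 0 in GF kidney (highest other 2) and 0 in chd8-/- kidney (highest other 0).

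The first pattern is that the library labelled kidney germ-free replicate 2 and kidney chd8-/- replicate 1 lay on the other group's side for the genes that were on or off in chd8-/- intestine, and over 12382 genes the first was nearest to chd8-/- replicate 2 (Spearman correlation across genes 0.966) and the second to GF replicate 1 (0.941). RNA of another library mixed into the first is argued against, because genes on only in CV stood there at 1.19% of the median of the kidney CV libraries. An exchange of the labels of these libraries would place CHD8 of kidney chd8-/- replicate 1 among the wild type libraries, but it held 28.3 CPM, the lowest of the 9, while CHD8 of the first library (31.6 CPM) went with the on or off genes. A mixture of parents is an open alternative, since the on or off state and the CHD8 level parted in 1 of the 9 kidney libraries and intestine GF replicate 2, with a wild type CHD8 level of 59.4 CPM, held 3 of the 14 genes on only in chd8-/-, and a single wrong label on the first library also stays open. These cannot be told apart, because 1 library per group shows the pattern and the labels do not name the parents of each library.

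The second pattern is the 1903 calls in chd8-/- intestine. Candidate explanations are loss of chd8, rearing, a batch of the separately listed chd8-/- libraries and linked sequence variants. Different parents of the chd8-/- and CV fish also stay open as untested, since the labels do not name the parents of each library. Of the 200 nearest neighbours of chd8 in the gene order of another assembly (GRCz12tu), 26 were called (13%, against 9% of other genes, two-sided Fisher's exact p = 0.0612), which is 1.98% of the matched calls. The share among placed genes is void by itself, because 69.7% of tested and 68.8% of called genes could be placed, under the 80% needed. Outside these neighbours 1284 calls were placed (67.5% of all 1903), and the other 593 could not be placed. A window of 200 genes cannot hold most of 1903 calls under any cause, so this test cannot decide on linked variants. Growth protocols give no contrast, as 0 chd8-/- libraries shared theirs with a CV library, so genotype, rearing and any batch cannot be told apart. On the genes called in intestine, kidney chd8-/- replicate 1 had a mean signed log2 difference from kidney CV of −0.042, within the range of the CV libraries (−0.133 to 0.077). Replicates 2 and 3 had 0.588 and 0.613. The value of chd8-/- replicate 1 would speak against loss of chd8 as the whole cause if the label of that library were certain. GF replicates 1 and 3 had 0.059 and 0.056. The library labelled kidney germ-free replicate 2 had 0.567, with a low CHD8 level (31.6 CPM). Kidney chd8-/- replicate 1 also had a low CHD8 level (28.3 CPM), which went with its label. The score thus did not follow CHD8 in that library.

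The third pattern is the lower interferon-response list in GF intestine and kidney. All 3 immune cell lists had medians above 0.5 times the interferon median in both tissues (value 3). Their lower quartiles in intestine (macrophage −0.34, neutrophil −0.39, lymphoid −0.3) and kidney (−0.85, −0.62 and −0.58) also lay above the interferon medians of −0.90 and −1.59. In the intestine these list values argue against a general fall of immune cells as the whole cause, for the genes of these lists only. The macrophage gene MPEG1 held 72.4 CPM in intestine CV replicate 3 (germ-free table), more than in any other intestine library. In CV replicate 2 it lay within the range of the GF libraries. CV replicate 3 also stood highest on the interferon list (0.85), and the interferon median was −0.66 without it. Loss of a few cells active in the interferon response could leave such broad lists unmoved and stays open. The kidney comparison was not repeated without CV replicate 1, so it decides nothing. Both cuts were set after the values were seen. A single CV library may account for much of the kidney value, since 40.9% of it was left without kidney CV replicate 1 (−0.65). Reassigning the GF labels within each tissue gave a two-sided exact permutation p of 0.01 over 400 assignments (smallest possible 0.005), an adjusted p of 0.16 over 48 lists, which would need 10 lists at a p of 0.01 to pass, and a joint permutation p of 0.325, which cannot go under 0.2, so chance cannot be told apart. By the same permutation the thrombocyte list had a p of 0.005 and the podocyte list 0.01. Antibiotics, washes and absence of microbes were given together and stay open as untested, and the kidney value includes the library labelled kidney germ-free replicate 2.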

How the results depend on the processing

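The fits without a pair of kidney libraries were chosen after the data were seen, and all other settings were planned. Directions of the named genes mostly held: of 1547 values over 107 gene results, 1370 kept direction and side of the threshold, 86 lost the call, 71 gained one and 20 turned, and DESeq2 size factors changed 0 of the 107. GF intestine had 0 calls by edgeR, and 3 with library size only, without a filter, with the stricter filter or with all 3 groups in 1 fit, 35 in DESeq2, and 0 to 2 without 1 library. GF kidney had 0, and 1 without a filter or with all 3 groups in 1 fit, 176 in DESeq2, 944 without CV replicate 1 and the library labelled kidney germ-free replicate 2, and 0 to 0 without 1 library. The 1903 calls of chd8-/- intestine became 1154 with a 2-fold minimum and 741 to 3069 without 1 library. chd8-/- kidney had 0, and 4 without a filter, 1 with all 3 groups in 1 fit, 245 in DESeq2, 2178 without CV replicate 1 and chd8-/- replicate 1, and 0 to 139 without 1 library. The fall of CHD8 in intestine ran from −0.70 to −0.51 without 1 library. Lists called by camera (19, 28, 17 and 26) became 0 in each comparison with an estimated correlation, and 0, 0, 2 and 2 with fry, which asks another question, and GF kidney had 18 to 30 without 1 library. The tissue difference of the GF response had 0 to 2 calls without 1 library and 3 without the kidney pair, and that of chd8-/- 13 to 64 and 318. Genes called in both comparisons of a tissue were 0, but 1 without a filter in each, and 15 in intestine and 46 in kidney with DESeq2.

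Same-numbered libraries did not deviate together (correlations −0.29 to 0.048), so their numbers do not pair them. With the replicate block CHD8 stood at −0.604 (edgeR adjusted p = 0.0568, against 0.00767 to 0.0309 under the other settings over all libraries) and chd8-/- intestine had 1344 calls, while the tissue difference of chd8-/- had 7, of which 0 were more positive and 7 more negative in kidney. Under that block isg15, igldcp and ifit8 were called, and cyp2x8 (adjusted p = 0.096), hce2l2 (0.0977), pvalb9 (0.107), scpp5 (0.107), helz2a (0.14) and ifi27.6 (0.279) were not. The glucocorticoid list of chd8-/- intestine was not called either (0.0794). Without a filter the tissue difference calls of helz2a (edgeR adjusted p = 0.0575) and scpp5 (0.073) were also lost. The same held without kidney CV replicate 1 and chd8-/- replicate 1 (0.0592 and 0.0905).

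Values that turned were those of genes that did not pass, with ranges over fits without 1 library. In GF intestine FABP2 ran from −0.32 to 0.12 (without CV replicate 1) and ANGPTL4 from −0.27 to 0.30 (without CV replicate 1), with 0.072 without GF replicate 3, 0.03 with library size only, 0.003 with the stricter filter, 0.059 with voom and 0.066 with the replicate block. In GF kidney CHD8 ran from −0.20 to 0.13 (without the library labelled kidney germ-free replicate 2; 0.09 without the pair) and SPI1 from −0.61 to 0.42 (without CV replicate 1; 0.51 without the pair). RUNX1 ran there from −0.17 (without GF replicate 3) to 0.56, with −0.010 without CV replicate 3, and SAA2 from −1.03 to 0.56 (without CV replicate 1), with 0.25 without GF replicate 3. In chd8-/- intestine FABP2 ran from −0.023 (without CV replicate 1) to 0.44. In chd8-/- kidney SPI1 ran from −0.70 to 0.32 (without CV replicate 1; 0.24 without the pair) and RUNX1 from −0.036 (without chd8-/- replicate 3) to 0.48, with −0.006 without CV replicate 3. The cause was not tested. In simulation 10% (GF) and 2% (chd8-/-) of 2-fold changes were found in kidney and 35% and 57% in intestine, where the biological coefficient of variation was 29.6% and 22.5% against 34% and 35.9% in kidney. Neither depth nor replicate number was varied.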

Other observations

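The fits without pairs of libraries and the values per library of single genes in this part were chosen after the results were seen, while the other genes follow the rule for called genes of a list. Other genes of chd8-/- intestine moved within lists whose members went both ways. The circadian repressor gene cry3a fell from 289 ± 47.6 to 82.8 ± 4.73 CPM (n = 3 each, log2 fold change −1.80, SE 0.17, edgeR adjusted p = 0.000172). Of 36 clock genes 3 rose and 7 fell (7 and 10 adjusted over the list alone), with a median of 0.12, a mean of −0.19 and no call of the list (camera adjusted p = 0.958), and the median was −0.01 with library size as the only scaling. FKBP5, a target of the glucocorticoid receptor, fell from 118 ± 49.7 to 20.3 ± 6.38 CPM (−2.54, SE 0.35, 0.0027), while SOCS1, a brake on cytokine signalling, rose from 4.62 to 11.9 CPM (1.36, SE 0.19, 0.00164). The glucocorticoid list was higher (19 genes, 4 rose and 1 fell, or 5 and 1 adjusted over the list alone, median 0.38, adjusted p = 0.0492, and adjusted p = 0.892 with an estimated correlation). That call was lost without CV replicate 2 (0.11) or 3 (0.124) in the numbering of the chd8-/- table and without chd8-/- replicate 1 (0.126). The class I histocompatibility gene mhc1zba fell from 192 to 45.4 CPM (−2.08, SE 0.24, 0.000628), opposite to mhc1zda, and the antigen presentation list did not pass (20 genes, median −0.20, 0.958).

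Single genes of other lists were also called in chd8-/- intestine. The apolipoprotein gene apoa4a rose from 23.1 to 64.0 CPM (log2 fold change 1.47, SE 0.16, edgeR adjusted p = 0.000343), and PDK2, a kinase that holds back glucose oxidation, fell from 97.0 to 32.3 CPM (−1.59, SE 0.16, 0.000201, for 1 of 2 genes with this symbol). The fatty acid oxidation list did not pass (40 genes, 2 rose and 6 fell, or 3 and 8 adjusted over the list alone, median −0.13, camera adjusted p = 0.15), nor did lipid absorption (37 genes, 3 rose and 1 fell, median 0.17, 0.172). The endothelial receptor gene tek rose from 6.06 to 17.2 CPM (1.51, SE 0.20, 0.00116) and the inflammatory caspase gene caspb from 15.5 to 40.5 CPM (1.39, SE 0.21, 0.00234). NOS1, the neuronal nitric oxide synthase gene, fell from 73.6 to 32.3 CPM (−1.19, SE 0.21, 0.0066). The gut hormone gene CCK rose from 3.42 to 7.59 CPM (1.16, SE 0.26, 0.0195), a call lost without CV replicate 2 (0.0573), chd8-/- replicate 1 (0.081) or chd8-/- replicate 2 (0.0986).

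Some values per library stood apart within groups (TMM over 9 libraries, CV numbered as in the germ-free tables). FKBP5 held 21.1, 73.8 and 199 CPM in the kidney chd8-/- libraries, and over the 6 libraries of the GF comparison it held 157, 152 and 148 CPM in CV, 47.8 and 48.1 CPM in GF replicates 1 and 3 and 70.9 CPM in the library labelled kidney germ-free replicate 2. RSAD2 held 29.6, 36.5 and 36.8 CPM in chd8-/- intestine against 1.42, 8.26 and 7.72 CPM in CV intestine, and 0.293, 0 and 1.2 CPM in chd8-/- kidney against 3.09, 5.46 and 5.69 CPM in CV kidney. The embryonic globin gene hbae3 ran from 79.7 to 96.6 CPM in chd8-/- intestine and from 142 to 187 CPM in CV intestine. In kidney it ran from 128 to 558 CPM in chd8-/- and from 163 to 342 CPM in CV. With 1 pair of kidney libraries at a time left out, edgeR called 944 genes in GF kidney without CV replicate 1 and the library labelled kidney germ-free replicate 2, and 0 to 4 for the other pairs. In chd8-/- kidney it called 2178 without CV replicate 1 and chd8-/- replicate 1, and 0 to 30 for the other pairs.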
